A study of Rattus norvegicus with 6 samples.

How the data were processed

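PolyA RNA was profiled in 6 libraries of rat bone marrow MSCs held in hydrogel for 48 h, 3 at 2 kPa (soft) and 3 at 18 kPa (stiff). The design text speaks of quadruplicates; 3 libraries per group were analysed here. Per the labels, cells were taken out of the hydrogel and libraries were made with a QIAseq FX Single Cell RNA Library Kit, then read on an Illumina HiSeq instrument. Whether a replicate is a separate culture or animal is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

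The deposited table held FPKM (fragments per kilobase of gene, scaled to library size) for 33589 rows, of which 706 carried identifiers of unannotated transcripts. The submitters' processing notes name Bowtie 0.12.9, Cufflinks 2.1.1 and HTSeq without a version. Those notes name the mouse builds mm10 and GRCm38, while the table carries rat Ensembl identifiers and rat gene names and names no build, so coordinates are printed as the table gives them. Strand handling and treatment of multiply mapped reads are not given in the sources used here, so genes with near-identical copies and overlapping genes are reported as uncertain. A gene name table of another assembly held no identifiers that matched and was not used.

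FPKM times gene length gave whole multiples of a single step in each library for 100% of values within 0.0001 of a whole number, so the reads per gene were recovered. Recovered totals were 16691693, 16161626 and 16092354 reads in soft replicates 1 to 3 and 14966354, 16163863 and 16711527 in stiff replicates 1 to 3. The library size implied by the FPKM was between 0.995 and 1.01 times the column's own total. For a gene of 1 kb, 3 reads corresponded to between 0.179 and 0.201 FPKM. FPKM are not counts, so the test was made on log2(FPKM + 1), and recovered reads served only for depth, checks and an added alternative. A fold change on this scale understates the change of low genes; fold values in the text are ratios of mean FPKM.

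Genes with a mean of at least 1 FPKM over the 6 libraries were kept, 12713 in number. Stiff was compared with soft in limma 3.58.1 under R 4.3.3, with group as the only term, an intensity trend in the moderated variance, two-sided tests and Benjamini-Hochberg adjustment at 0.05. No comparison of ranks alone was used, since 3 against 3 libraries cannot go below an exact two-sided p of 0.1. No 2 libraries of a group were alike within sampling noise, as the chi-square per degree of freedom over genes was 3.71 or more in every pair. On simulated data of the same shape over 12713 genes, 63% of 100 genes changed by 1 on the log2 scale were found and 28% of 100 changed by 0.5, 4 of 95 calls were false, none had the wrong sign, and no call was made without any change. A planted list of 25 genes raised by 0.3 was called (adjusted p = 9.5e-13), and 0 of 30 random lists were. Each gene was simulated independently, so these results cannot show how the list test performs where members of a list are correlated. All genes of similar abundance were given the same mean spread, with no structure across libraries. The shares found and the false calls may therefore differ in the real data.

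Before the data were examined, 31 gene lists with 695 genes were fixed, together with the main test, the alternatives and the rule for naming genes; 23 of the genes were not analysed here for want of a matching name. Lists with at least 5 measured members, 28 in all, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. The lists covered mitosis and G2/M, DNA replication, SRF/MRTF and contractile genes, YAP/TAZ targets, mechanosensors, focal adhesion, structural matrix, matrix proteases, TGF-beta targets, Wnt targets, MSC markers, osteoblast, cartilage and adipocyte genes, paracrine factors, cytokines, interferon-stimulated genes, immediate early genes, heat shock, unfolded protein response, antioxidant, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, autophagy and lysosome, p53 and apoptosis, and leukocyte, endothelial, erythroid and neural markers. Named genes were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM; in each list, up to 4 called members with the smallest p or, with none called, the 2 most abundant; Ccn2, Ccn1, Ankrd1, Yap1, Runx2, Pparg, Col1a1 and Acta2 where measured; and the 5 most abundant genes of each group. One gene that this rule names is not reported here.

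The alternatives changed the pseudocount, the level filter, the scaling, the variance model, library weights and the threshold, added the replicate number as a block, and left out each library in turn. Chosen after seeing the data were voom on recovered reads, FPKM from each library's own total, removal of a trend with gene length, protein-coding genes alone, camera on ranks, and the oxidative phosphorylation list without Ndufa1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.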

Results

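The series measured polyA RNA of rat bone marrow mesenchymal stem cells (MSCs, stromal cells that can form bone, cartilage and fat) kept for 48 h inside a hydrogel that the labels call SA. The hydrogel was either soft, at 2 kPa, or stiff, at 18 kPa, and each group had 3 libraries here. Reads recovered from the deposited FPKM came to between 14966354 and 16711527 per library, and between 17497 and 17865 genes had at least 1 read. The first principal component of log2(FPKM + 1), with 30.2% of the variance, placed the soft libraries at -20.9, -8.22 and -7.98 and the stiff ones at 10.3, 12.6 and 14.2. The second, with 24.1%, cut across the groups. Spearman correlations between libraries, taken across genes, ran from 0.974 to 0.987. Soft replicate 1 stood farthest out on the first component and had 2.15% of its reads in mitochondrial genes, against 2.85% to 3.33% in the other libraries. FPKM summed to 452787, 456786 and 457306 in the soft libraries and to 467372, 468966 and 478304 in the stiff ones.

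**Figure D1:**
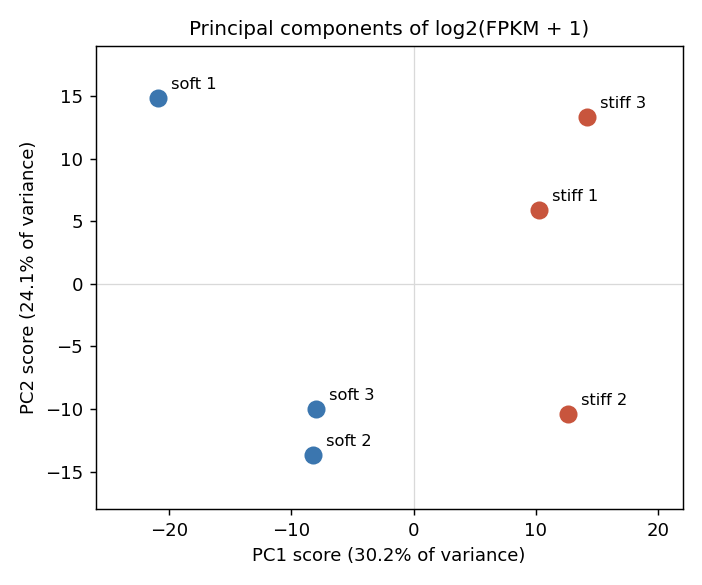
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), in arbitrary score units, 1 point per library, soft in blue and stiff in red. The soft libraries lie between -20.9 and -7.98 on the first component and the stiff ones between 10.3 and 14.2, while the second component does not part the groups.

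The comparison of stiff with soft asks how the stiffness of the surrounding gel changed gene expression in these cells. In stiff gel smooth muscle and contractile genes led the rises. Acta2, which encodes smooth muscle actin, went from 47.0 ± 3.49 to 123.5 ± 7.82 FPKM (SD, n = 3 per group), 2.63-fold. Cnn1 (calponin) rose 2.74-fold, Actg2 (enteric smooth muscle actin) 2.50-fold and Tagln (transgelin) 2.11-fold. Ccn2, a secreted matricellular protein and a widely used YAP/TAZ target, rose from 195.0 ± 3.99 to 375.3 ± 1.55 FPKM, and 11 of 25 measured genes of mitosis rose. The chemokine gene Ccl6 fell from 27.1 ± 2.01 to 13.0 ± 1.01 FPKM, the chloride channel gene Best1 from 8.82 ± 0.354 to 4.05 ± 0.280 FPKM, and Ccn3, a relative of Ccn2, from 47.7 ± 2.03 to 27.6 ± 0.836 FPKM. Genes that define the bone, cartilage and fat lineages mostly did not pass the test.

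With limma on log2(FPKM + 1), 182 of 12713 tested genes passed a Benjamini-Hochberg adjusted p of 0.05, 128 higher and 54 lower in stiff gel. Of these, 6 rose and 8 fell by at least 1 on the log2 scale, and the median absolute change of the 182 was 0.53. Protein-coding genes made up 127 of the rises and 45 of the falls. In all 182, the 3 libraries of one group lay above the 3 of the other. The threshold itself favours such genes, so this adds no separate support for the calls. Over all tested genes 22.6% were parted this way, against 10% by chance. The split of calls shifted with scaling, to 87 higher and 69 lower when each library's FPKM was scaled to the same sum, and to 103 and 68 after quantile normalization. Without soft replicate 1, which stood apart, 116 genes were higher and 43 lower. The counts were 43 and 11 without soft replicate 2 and 27 and 11 without soft replicate 3. They were 19 and 7, 33 and 13, and 28 and 9 without stiff replicates 1, 2 and 3.

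**Figure D2:**
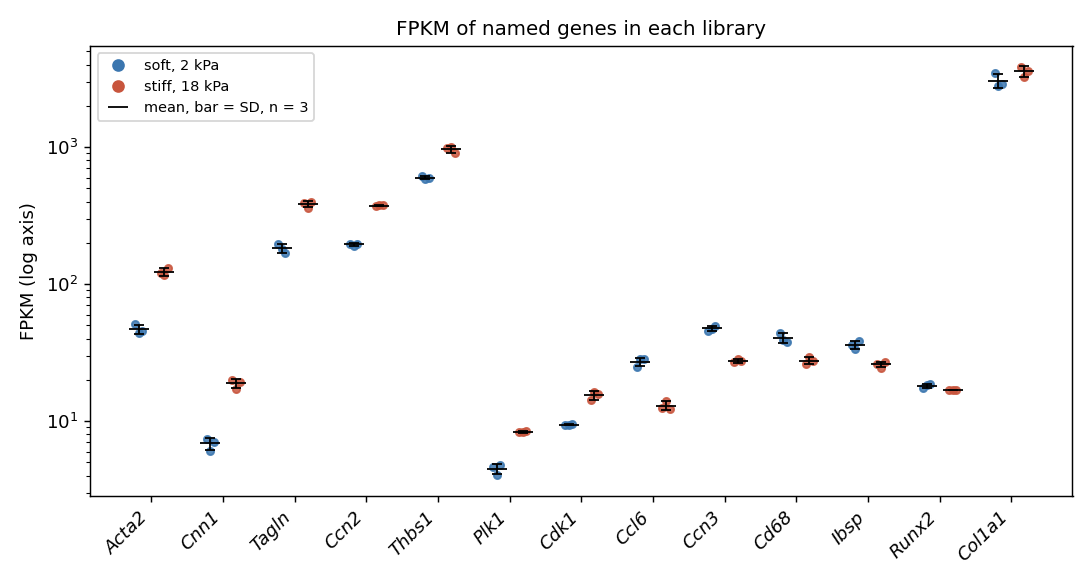
FPKM on a log axis for 13 of the named genes, 1 point per library, soft (2 kPa) in blue and stiff (18 kPa) in red, with the mean as a black line and the SD as its bar (n = 3). Acta2 moves from 47.0 to 123.5 FPKM and Ccn3 from 47.7 to 27.6 FPKM with no overlap of libraries. Runx2 and Col1a1 did not pass the test, though the Runx2 libraries did not overlap either.

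The 10 largest rises among genes at 5 FPKM or more comprised Acta2 (log2 fold change 1.38, SE 0.0727, adjusted p = 0.00111), Cnn1 (1.33), the snoRNA gene RF01161 (1.15), Cd55 (1.13), Actg2 (1.12), Tagln (1.07), Slco2a1 (1.00), Trib3 (0.95), Ccn2 (0.94, SE 0.0422, adjusted p = 0.000673) and Lgr5 (0.86). Of these, Cd55, which shields cells from complement, went from 9.77 ± 1.03 to 22.5 ± 1.12 FPKM, and Slco2a1, a prostaglandin transporter, from 4.70 ± 0.136 to 10.4 ± 0.801 FPKM. Acta2 (ENSRNOG00000058039) lies on chromosome 1 from 252537615 to 252550394, and Ccn2 (ENSRNOG00000015036) on chromosome 1 from 21851660 to 21854773, in coordinates whose build the table does not name. Of the 57 named genes that passed the test, 15 also passed in all 6 fits that left out 1 library, among them Acta2, Actg2, Cnn1, Myl9, Tagln, Ccn2, Ccdc80, Cd55, Slco2a1, Col11a1, Thbs1, Ccn3, Ccl6 and Best1. Another 8 passed in none of those fits: Adgre1, Ccl20, Col15a1, Ctsb, Ibsp, Ndrg1, Plin2 and AC129460.1. The adjusted p of these 8 reached between 0.131 and 0.210 in the least favourable fit. A further 21 passed in only 1 of the 6 fits. These were Lgr5, Sfrp1, Rrm2, Tk1, Chac1, F3, Vim, Itga11, Thbs2, Mmp14, Tgfbi, Acan, Hmox1, Vegfa, Lgals3, Adm, Cd68, Cd53, RF01161, LOC100912008 and AC114233.2.

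Among the 10 largest falls, LOC100911130, annotated as like Tim17-B, a subunit of the mitochondrial import machinery, was at 12.2 ± 7.21 FPKM in soft and 0.568 ± 0.0964 in stiff gel (log2 fold change -2.95, adjusted p = 0.0106). The uncharacterized LOC100912008 was at 6.37 ± 3.63 and 0.291 ± 0.194 FPKM (-2.38). Both values are uncertain, since copies of a gene can share reads and levels varied several-fold among the soft libraries. Next came the pseudogene AC114233.2 (-1.06), Ccl6 (-1.01, SE 0.0810, adjusted p = 0.00337) and AABR07028970.2, whose stiff level was 0.438 times the soft one. The others were Best1 (-0.96), the microRNA gene AC129460.1 (-0.85), the snoRNA gene RF00016 (-0.81), Col15a1 (-0.80), which encodes a basement membrane collagen, and Ccn3 (-0.77, SE 0.0564, adjusted p = 0.00295). AC114233.2 lies on chromosome 10 from 70794893 to 70795241, beside Ccl6 at 70797124 to 70802782 on the same strand, so the pair is not certain to be 2 separate changes. Small RNA genes are poorly sampled by polyA libraries, and RF01161, RF00016 and AC129460.1 are uncertain for that reason.

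Of 23 measured genes of the contractile actin cytoskeleton and of the SRF/MRTF transcription factors, 10 rose and none fell, and 18 rose when adjusted over the list alone. All 23 had log2 fold changes above 0, with a median of 0.28, and 22 did at equal FPKM sums or after quantile normalization. After Acta2, Tagln and Cnn1 came Myl9, a myosin light chain, from 52.6 ± 2.32 to 93.7 ± 7.40 FPKM. The camera test with a preset correlation gave an adjusted p of 2.0e-20 and lost the call with an estimated correlation (adjusted p = 0.0623 with an estimated correlation).

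YAP/TAZ-TEAD targets rose in 6 of 20 measured members (6 higher and 1 lower adjusted over the list alone), with Ccn2 followed by Ccdc80 (log2 fold change 0.62), F3 (0.53), the tissue factor gene, and Ccn1 (0.49), from 95.6 ± 2.31 to 134.3 ± 4.40 FPKM. The list's median was 0.13, and 0.08 at equal FPKM sums, where 13 rather than 14 genes lay above 0 (camera adjusted p = 0.000952, 0.0700 on ranks; adjusted p = 0.143 with an estimated correlation). Ankrd1, another common target, lay under the level filter at 0.0909 FPKM in soft and 0.153 FPKM in stiff gel. None of 20 mechanosensor genes (channels, nuclear lamina and linker proteins, YAP and MRTF cofactors) passed limma's test (3 had an unadjusted p under 0.05, and 1 passed with voom). Adjusted over the list alone 1 rose, and camera gave an adjusted p of 0.716. Yap1 itself was at 74.2 ± 13.2 and 70.5 ± 3.96 FPKM (log2 fold change -0.06, adjusted p = 0.864), Rhoa at 267.3 and 295.0 FPKM and Lmna at 201.6 and 214.9 FPKM.

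Mitotic and G2/M genes rose in 11 of 25 measured members, and in 24 of 25 when adjusted over the list alone, with a median log2 fold change of 0.52 and all 25 above 0. Plk1, a mitotic kinase, went from 4.48 ± 0.393 to 8.36 ± 0.0954 FPKM, Cdk1 from 9.43 ± 0.0556 to 15.4 ± 1.10, Ccnb1 (cyclin B1) from 5.30 ± 0.268 to 9.43 ± 0.863 and Cdc20 from 6.15 ± 0.382 to 10.2 ± 0.371. Camera gave an adjusted p of 4.7e-24 (adjusted p = 0.0623 with an estimated correlation). Of 23 genes of DNA replication, 2 rose, Rrm2 (0.58) and Tk1 (0.70), which supply deoxynucleotides, and 7 rose when adjusted over the list alone (median 0.21; camera adjusted p = 3.6e-06; adjusted p = 0.143 with an estimated correlation).

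**Figure D3:**
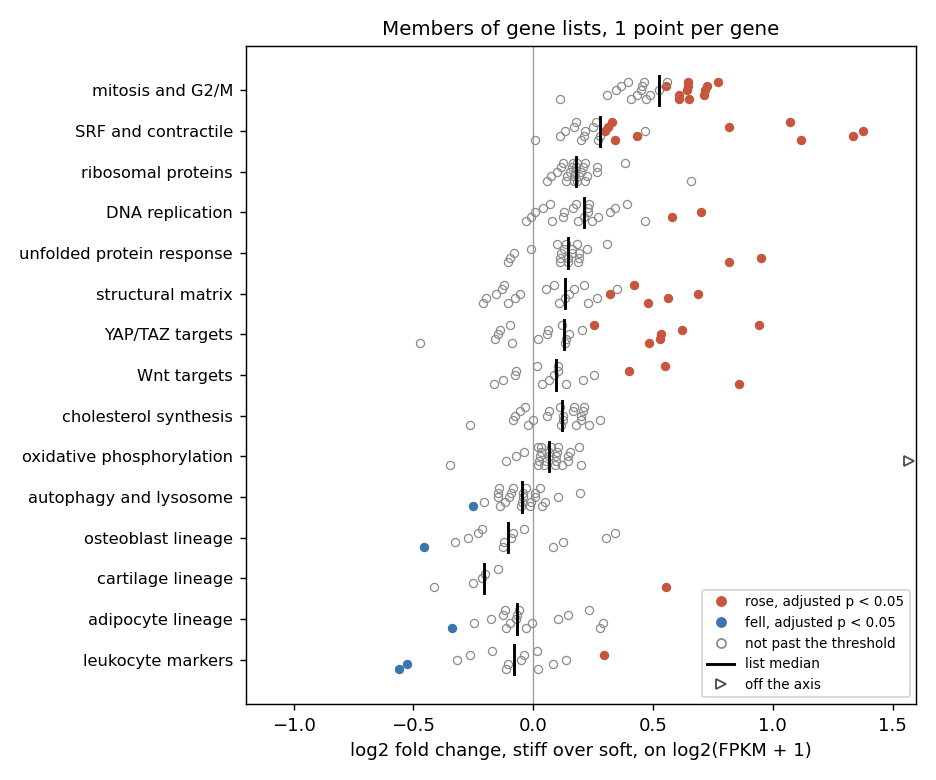
Log2 fold change of stiff over soft on log2(FPKM + 1) for each measured member of 15 gene lists, 1 point per gene, filled where adjusted p was under 0.05 and with a black line at the list median. Every mitotic member lies above 0 around a median of 0.52, the contractile list has 10 filled points reaching 1.38, and the lineage lists hold 1 filled point each. The arrowhead is Ndufa1, off the axis at 3.94.

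Structural matrix genes rose in 5 of 23 measured members (8 higher and 1 lower adjusted over the list alone), with a median of 0.13, which was 0.08 at equal FPKM sums and 0.04 after quantile normalization (camera adjusted p = 0.000339; adjusted p = 0.183 with an estimated correlation; 0.0580 after quantile normalization). Of the 23, 15 lay above 0 at each of these scalings. The 1 lower gene was Postn, at 2995.3 ± 227.2 in soft and 2586.9 ± 137.2 FPKM in stiff gel (-0.21). Thbs1 (thrombospondin 1) rose from 598.3 ± 15.9 to 965.9 ± 51.2 FPKM, Thbs2 from 887.2 ± 15.4 to 1109.9 ± 30.5, Col11a1 from 67.3 ± 1.04 to 99.9 ± 2.59 and Col8a1 from 26.6 ± 0.784 to 37.5 ± 1.27. Col1a1, the main collagen I gene, was at 3061.5 ± 372.5 and 3579.3 ± 314.3 FPKM (0.23, adjusted p = 0.334). Among 23 matrix proteases and their inhibitors 2 rose, among them Adamts1 (0.49), a secreted metalloproteinase. Mmp14, a membrane-bound collagenase, fell (-0.38), with 2 higher and 5 lower adjusted over the list alone and a camera adjusted p of 0.403. In the TGF-beta target list of 21, 2 rose, among them Ltbp1 (0.48), and Tgfbi fell (-0.39), while 2 rose and 1 fell adjusted over the list alone. The median was -0.04 and the mean 0.01, and camera gave an adjusted p of 0.716. Itga11, a collagen receptor subunit, was the only one of 21 focal adhesion genes to rise (0.32; 2 adjusted over the list alone; camera adjusted p = 0.179). Vim rose (0.36) among 17 MSC markers, of which 3 rose adjusted over the list alone (camera adjusted p = 0.0598).

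Wnt target and feedback genes rose in 3 of 16 measured members: Nkd2 (0.55) and Sfrp1 (0.40), both known as inhibitors of the pathway, and Lgr5 (0.86), from 2.61 ± 0.369 to 5.60 ± 1.08 FPKM (5 adjusted over the list alone; median 0.09, and 0.05 at equal FPKM sums, where 10 rather than 12 lay above 0; camera adjusted p = 0.00303, 0.0556 on ranks; adjusted p = 0.143 with an estimated correlation). The unfolded protein response list had 2 rises among 22, Trib3 and Chac1 (0.82), which are also induced by ATF4 under amino acid shortage, and 7 adjusted over the list alone (median 0.15, and 0.10 at equal FPKM sums or after quantile normalization; camera adjusted p = 6.8e-06; adjusted p = 0.0743 with an estimated correlation).

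Of 26 cytosolic ribosomal protein genes none passed limma's test over all genes (18 had an unadjusted p under 0.05, and 1 passed with voom) and 14 rose adjusted over the list alone. All 26 had log2 fold changes above 0 with a median of 0.18, which was 0.13 at equal FPKM sums and 0.09 after quantile normalization, where 25 lay above 0. Rplp0 was at 1254.5 ± 33.6 and 1433.9 ± 46.3 FPKM and Rplp1 at 984.4 ± 33.5 and 1186.7 ± 125.2 FPKM (camera adjusted p = 6.6e-11; adjusted p = 0.145 with an estimated correlation). Across all tested genes, which are not independent replicates, log2 fold change and gene length had a Spearman correlation of -0.146. Cholesterol synthesis had no limma call among 22 genes over all genes tested (7 at an unadjusted p under 0.05, 0 with voom) and 2 higher and 1 lower adjusted over the list alone (median 0.12, and 0.08 at equal FPKM sums; camera adjusted p = 0.0171; adjusted p = 0.145 with an estimated correlation). Hmgcs1 was at 75.9 and 85.0 FPKM and Insig1 at 59.8 and 56.7 FPKM. Oxidative phosphorylation had no limma call among 27 genes by either count (3 at an unadjusted p under 0.05, 0 with voom), with 23 genes above 0 as deposited but 16 at equal FPKM sums or after quantile normalization. Its median was 0.07, against 0.02 at equal FPKM sums and 0.03 after quantile normalization, and its camera adjusted p 0.0208 (adjusted p = 0.474 with an estimated correlation). That call was also lost at equal FPKM sums (0.105), after quantile normalization (0.460), with array weights (0.114), with fry (0.232), with the length trend removed (0.0630) and without stiff replicate 3 (0.292). Cox4i1 was at 312.3 and 339.2 FPKM, Atp5f1b at 386.2 and 394.1 FPKM, and the mitochondrial COX1 at 8836.3 and 10274.2 FPKM. The autophagy and lysosome list was lower in stiff gel, with Ctsb, a lysosomal protease, falling from 1773.0 ± 23.1 to 1490.1 ± 32.5 FPKM as the only call of 24 by either count (median -0.05; camera adjusted p = 0.0297; adjusted p = 0.183 with an estimated correlation). The median was -0.09 at equal FPKM sums and -0.08 after quantile normalization, with 3 and 4 members above 0, against 7 as deposited. The adjusted p rose to 0.0537, 0.0868 and 0.0558 without soft replicate 3, stiff replicate 1 and stiff replicate 2, to 0.0738 without the variance trend and to 0.0700 on ranks.

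Few lineage genes passed the test. Among 14 measured osteoblast genes, Ibsp, a bone matrix sialoprotein, fell from 36.0 ± 2.55 to 26.0 ± 1.24 FPKM (2 lower adjusted over the list alone; camera adjusted p = 0.0529). The regulator Runx2 was at 18.1 ± 0.606 and 17.0 ± 0.00499 FPKM (-0.09, adjusted p = 0.485). Of 6 cartilage genes over the filter, Acan, the aggrecan gene, rose (0.56; 1 higher and 2 lower adjusted over the list alone; median -0.21; camera adjusted p = 0.0858). Plin2, a lipid droplet protein gene, fell (-0.34) as the only one of 17 adipocyte genes by either count (camera adjusted p = 0.230). Pparg was at 4.22 ± 0.419 and 3.61 ± 0.0883 FPKM (adjusted p = 0.415).

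Secreted factors and stress genes gave few calls. Lgals3 (-0.39) and Vegfa (-0.33) fell among 20 paracrine factors (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.750). Ccl20 rose (0.39) among 20 cytokines (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.178). Adm rose (0.34) and Ndrg1 fell (-0.26) among 28 glycolysis and hypoxia genes (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.112). Hmox1, the haem oxygenase gene, fell from 613.8 ± 11.1 to 496.8 ± 7.72 FPKM among 22 antioxidant genes (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.151). None of 16 interferon-stimulated genes passed limma's test by either count (3 at an unadjusted p under 0.05, 0 with voom; camera adjusted p = 0.598), with Ifi27 at 215.3 and 250.0 FPKM and Irf9 at 16.5 and 15.5. None of 15 heat shock genes passed over all genes (2 at an unadjusted p under 0.05, 1 with voom), and 1 fell adjusted over the list alone (camera adjusted p = 0.716). Hsp90ab1 was at 438.3 and 454.0 FPKM and Serpinh1 at 384.8 and 430.2. Of 23 immediate early genes none passed over all genes (8 at an unadjusted p under 0.05, 2 with voom), and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.791). Junb was at 153.3 and 135.5 FPKM and Jund at 93.9 and 99.2. Of 17 p53 and apoptosis genes none passed over all genes (2 at an unadjusted p under 0.05, 1 with voom), and 1 rose adjusted over the list alone (camera adjusted p = 0.801). Cdkn1a was at 197.4 and 181.0 FPKM and Phlda3 at 123.7 and 128.4. In the heat shock list the median (0.05) and mean (-0.04) differed in sign, and in the immediate early list the median was negative while the mean was 0.03.

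Markers of other cell types were present. Of 14 measured macrophage and other leukocyte markers, Cd68 fell from 40.4 ± 3.47 to 27.7 ± 1.52 FPKM and Cd53 from 12.6 ± 1.15 to 8.20 ± 0.439 FPKM, while Adgre1 rose from 69.0 ± 1.85 to 84.9 ± 2.24 FPKM (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0529). The list was called lower with the filter at 5 FPKM (0.00960), after quantile normalization (0.0433), with array weights (0.0479), with fry (0.0317), with the length trend removed (0.0294), with protein-coding genes alone (0.0431), and without soft replicate 2 (0.0377) or stiff replicate 3 (0.0207). At an adjusted p of 0.05 it was not called in the other settings run for lists, among them an estimated correlation (adjusted p = 0.183), ranks (0.136), no level filter (0.141) and without stiff replicate 1 (0.128). Ccl6 and Lgals3, which also fell, are abundant in macrophages. Only 2 endothelial markers were over the filter, Egfl7 at 5.97 and 7.62 FPKM and Esam at 3.39 and 2.71. Of neural and Schwann cell markers 4 were over it, among them S100b at 61.8 and 64.2 FPKM and Ncam1 at 18.2 and 16.4. The erythroid list had 0, and none of the 6 passed limma's test (2 at an unadjusted p under 0.05, 0 with voom).

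The 5 most abundant genes in soft gel were COX1, Cxcl13, Fn1, Spp1 and Mgp, and in stiff gel COX1, Cxcl13, Col3a1, Mgp and Fn1. Cxcl13, a B cell chemokine, was at 5156.1 ± 870.8 and 5547.7 ± 606.2 FPKM (0.11, adjusted p = 0.742), Fn1 at 4881.1 and 4381.9, Mgp at 4547.0 and 4429.3 and Col3a1 at 4272.6 and 4684.0. Spp1 (osteopontin) was at 4831.8 ± 186.4 and 4002.5 ± 137.6 FPKM (-0.27, adjusted p = 0.0574). Of 28 lists tested, 10 were higher and 1 lower in stiff gel by camera with a preset correlation. None was called with an estimated correlation, where 8 had an unadjusted p under 0.05, and fry called 13. The estimate lay under the preset 0.01 for the unfolded protein response (0.00864), YAP/TAZ (0.00903) and cholesterol (-0.0345) lists. Their lost calls therefore cannot be put down to a correlation above the preset. In the other called lists the estimate ranged from 0.0126 (Wnt targets) to 0.229 (ribosomal proteins). The estimated setting raised p even where the estimate lay under the preset. For the unfolded protein response list the unadjusted camera p went from 1.2e-06 to 0.00796. A call lost in that setting therefore does not by itself show correlation among the members of a list.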

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

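Added after seeing the data were voom, own read totals, the length trend, protein-coding genes alone, camera on ranks and the list without Ndufa1. Higher and lower calls (128 and 54) became 71 and 21 with no level filter, 85 and 27 without the variance trend, 430 and 255 with array weights, 242 and 140 at an adjusted p of 0.1, and 220 and 113 with voom, of which 126 and 45 were among the original calls; with fewer libraries they ranged from 19 to 116 and from 7 to 43. They stayed within 1.5 times under the other scalings, pseudocounts, filter at 5 FPKM, robust variance, length trend and protein-coding settings. Deviations of same-numbered libraries from their group means correlated at 0.0552, 0.116 and -0.0785, and not every library matched its own number best. With 3 libraries per group this shows no clear pairing by replicate number but cannot exclude one, and the sources do not say. With the replicate block 78 and 27 genes were called and no list changed sides. Changes of at least 1 on the log2 scale (6 higher, 8 lower) became 12 higher at a pseudocount of 0.1, 13 and 20 with array weights and 16 higher with voom, while lower ones became 4 with no filter and 4 with the filter at 5 FPKM; without single libraries they ranged from 6 to 9 and from 3 to 11. Higher lists (10) became 0 with an estimated correlation and ranged from 9 to 11 without single libraries. The single lower list became 2 with the filter at 5 FPKM, with quantile normalization, with array weights, with voom and with the length trend removed, 4 at an adjusted p of 0.1, 3 with fry and with protein-coding genes alone, and 0 without the variance trend, with an estimated correlation and on ranks; it ranged from 0 to 3 without single libraries. Lists not called that passed at an adjusted p of 0.1 were the leukocyte markers, osteoblast and cartilage genes (lower) and MSC markers (higher). At 0.05 the leukocyte markers passed in some settings, as did osteoblast genes (lower with voom, with fry, with protein-coding genes alone and without stiff replicate 3), MSC markers (higher with voom, with fry and with the length trend removed) and glycolysis and hypoxia (higher with array weights and without soft replicate 1 or stiff replicate 2). With an estimated correlation their adjusted p was 0.183, 0.183, 0.183 and 0.622, in that order. There were 87 named genes, of which 57 were called. Of those 57, 25 lost the call without the variance trend, 24 with no filter, 16 with the replicate block and between 11 and 41 without single libraries. On ranks the Wnt and YAP/TAZ lists had camera adjusted p of 0.0556 and 0.0700. Without Ndufa1 the oxidative phosphorylation list was at 0.0350 by camera with the preset correlation, the only setting run for that shortened list. The full list, with Ndufa1, lost its call with an estimated correlation (adjusted p = 0.474) and in 6 other settings. The median log2 fold change of all genes lay farthest from 0 at equal FPKM sums, at -0.0447. Signs turned only in genes and lists that had not passed. Under quantile normalization Hsp90ab1 went to -0.0594, Atp5f1b to -0.0532 and Phlda3 to -0.00108, and Atp5f1b to -0.0208 at equal FPKM sums. Under quantile normalization the antioxidant (0.7996), glycolysis and hypoxia (0.864), heat shock (0.771), immediate early (0.876) and paracrine (0.771) lists turned down, with these adjusted p. Yap1 went to 0.0240 and Cxcl13 to -0.0325 with array weights. Without single libraries Yap1 ranged from -0.170 to 0.0743, Cxcl13 from -0.0333 to 0.201 (both turned without soft replicate 1) and Phlda3 from -0.0495 to 0.185 (turned without soft replicate 2, stiff replicate 1 or stiff replicate 3). The TGF-beta list turned up with array weights (0.959), without soft replicate 1 (0.804) and with fry (0.323), matrix proteases up with fry (0.810), mechanosensors down without soft replicate 2 (0.852), and immediate early genes down there (0.765) and with the length trend removed (0.996). Without single libraries the adjusted p of the TGF-beta, mechanosensor and immediate early lists ranged from 0.434 to 0.903, from 0.326 to 0.949 and from 0.199 to 1.00. With no filter more genes were tested and without a library fewer samples were; the cause was not tested for the other changes. Robust variance was not run for lists. With 3 libraries per group, changes of 0.5 on the log2 scale were found in 28% of simulated genes, a share that may not hold in the real data. Uncalled genes may still differ.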

Other observations

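The added lists, the splits for gene counts, the leukocyte marker tests and the test of switching genes were chosen only after the result was seen. A list of amino acid synthesis, transport and other ATF4-regulated genes, with tRNA ligases among them, was drawn up after the calls were seen. Of its 29 measured members, 10 rose and none fell (17 adjusted over the list alone). Trib3 and Chac1, already counted in the unfolded protein response list, were among the 10. The 10 also included Psat1 (1.59-fold) and Phgdh (12.3 ± 0.533 to 18.3 ± 0.697 FPKM), enzymes of serine synthesis, and Slc7a5, a leucine transporter (1.49-fold). Because the list was built from these samples, its camera p (adjusted p = 0.00268 with an estimated correlation) is not independent evidence. Of 12 tubulin genes, 4 rose (7 adjusted over the list alone), led by Tuba1b (111.3 ± 2.83 to 154.6 ± 4.04 FPKM), and of 6 caveolin and cavin genes Cavin1 (78.3 ± 2.05 to 103.4 ± 1.84) and Cav1 (53.1 ± 5.33 to 74.9 ± 4.62) rose, by either count. These lists carry the same caveat.

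In a list of 24 measured phagocyte surface and lysosome genes, also drawn up afterwards and sharing only Cd68 with the leukocyte markers, 7 fell, 1 rose and 16 did not pass (13 fell and 2 rose adjusted over the list alone). The median was -0.27, which, for a list built from the calls, is not independent evidence either. Gpnmb fell from 462.4 ± 11.8 to 296.8 ± 7.41 FPKM, Fcgr2b, an Fc receptor gene, from 7.89 ± 0.497 to 4.68 ± 0.208, Slc11a1 from 17.4 ± 1.09 to 12.0 ± 0.553 and Cybb, a subunit of the phagocyte oxidase, from 29.2 ± 2.36 to 20.6 ± 0.880, while Itgal rose from 5.78 ± 0.552 to 8.47 ± 0.263.

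A candidate explanation for the fall of Cd68 and Cd53 is a lower share of leukocytes in stiff gel. By a first criterion, that at least 6 of the other 12 measured markers have 95% intervals wholly above that of Cd68, the test was undecided, with 5. A second test, chosen after that count was known, argues against an equal fall of all the markers: their changes differed by more than their errors (Cochran Q 155.1 on 13 degrees of freedom; marker genes are not independent replicates), with Adgre1 at 0.30 (0.18 to 0.41) and Cd68 at -0.53 (-0.71 to -0.35), though Lyz2 (-0.32) and Tyrobp (-0.26) also lay wholly below 0. Q included Cd68 and Cd53, which were picked for their falls, so part of that difference was built in. When single libraries were left out, Adgre1 passed in 0 of 6 fits and Cd68 and Cd53 in 1 each. A lower share together with changed expression in the leukocytes that remain, or expression of some markers by the MSCs, cannot be told apart from these libraries, and the effect of stiffness on such cells stays open.

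The ribosomal protein list had a median of 0.18, but none of its 26 genes passed over all genes and its call was lost with an estimated correlation (adjusted p = 0.145). With a trend on gene length removed, the list's median was 0.18, as before, which argues against a smooth length trend over all tested genes as its whole cause. That trend was fitted with small RNA genes included, so a length effect particular to short mRNAs stays open. Leaving out any 1 library gave a median of 0.15 or more, which argues against a single library. The median depended on the scaling, at 0.13 with equal FPKM sums and 0.09 after quantile normalization, and which scaling is right was not tested. The correlation among these genes remains open, as does an effect of stiffness, which is a hypothesis only.

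In 44 tested genes with at least 100 reads in some library, levels switched, ranging over more than 16-fold within a group; Ndufa1, for example, was at 113.0, 0.573 and 1.73 FPKM in the soft libraries and at 137.1, 115.9 and 108.5 in the stiff ones. LOC-numbered or repeated symbols made up 52.3% of them and 2.19% of the other genes with as many reads (odds ratio 48.8), consistent with reads moving between copies of a gene. None of the 44 passed the test between groups, but the wide range within a group by which they were picked made a call unlikely from the start. LOC-numbered or repeated symbols made up 11 of the 182 calls, and 4 of the 8 falls of at least 1 on the log2 scale. For LOC103690033, similar to isoleucyl-tRNA ligase, which fell and is named here after its value was seen, the change in reads summed with the named gene Iars was 26.4 (-77.5 to 130.4), so its loss may be a transfer. For LOC100911130 the sum with Timm17b changed by -97.9 (-195.1 to -0.719), close to the copy's own change of -98.3 (-195.5 to -1.06). Timm17b was listed at 0 in all soft libraries and gained 0.334 reads (-0.594 to 1.26). This met the bound set beforehand against a transfer, as Timm17b did not gain the reads that the copy lost. How reads matching both genes were handled is unknown, so sharing that leaves Timm17b near 0 in both groups stays open.

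With 3 libraries against 3 there are 10 splits of the samples, too few for a share under 0.05. The real split called 182 genes, against 3 in the highest of the other splits, and was the only 1 of the 10 with as many. Every other split has soft and stiff libraries on both sides, so any group difference widens its spread and lowers its calls. Counts from those splits are therefore not a fair measure of chance. At an unadjusted p under 0.05 the gap was narrower, with 1960 genes in the real split and 1648 in that of soft 1, stiff 1 and stiff 3 against the rest. Those 3 libraries are the ones above 0 on the second component, which points to a structure of the samples across the groups. The real split called 14 genes changed by at least 1 on the log2 scale against 3, and 11 lists against 6 at the preset correlation. With an estimated correlation the real split called 0 lists.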
